A study of Mus musculus with 8 samples.

How the data were processed

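The series measured total RNA of female mouse brain at 3, 12 and 40 weeks of age. RNA was prepared with a silica column kit and DNase treatment, amplified from an oligo-dT primer with a T7 promoter and labelled with Cy3 or Cy5 during in vitro transcription, per the labels' protocols. The 8 samples were hybridised in pairs to 4 arrays of the Agilent whole mouse genome format on 2 slides. Each array held a 40-week sample in Cy5 and a younger sample in Cy3: 12-week samples on arrays 1 and 2 of slide 1, and 3-week samples on arrays 3 and 4 of slide 2. Sample titles also carry a code, A1B on arrays 1 and 3 and A2B on arrays 2 and 4. The code coincides with the position of the array on its slide, and the labels do not say what it stands for. They also do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

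The authors deposited intensity values on a linear scale, 1 per array feature and dye channel, made with Agilent Feature Extraction 11.5 per the submitters' processing notes, and treated the channels as single samples per the series design text. The settings for background, dye normalization and floor are not given in the sources used here. In the values, both channels of an array had medians within 0.032 log2 units of each other, while medians differed by up to 0.77 log2 units between samples, so arrays were not scaled to one another. The deposited table held 44397 features identified by feature number. The files do not pair these numbers with genes, and no table that does was used here. Gene list tests, checks of the female label by gene, and averages over the probes of a gene, all intended at the outset, were therefore not run, and each feature was tested as itself.

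Intensities were turned into log2 values, and each sample was shifted by its 75th percentile, as planned for samples whose medians differ. A level is therefore given relative to the upper quartile of its sample. Differences between ages were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 coefficient per age, all 8 samples, 2-sided), with the array as a random block through duplicateCorrelation. The correlation between the 2 samples of an array was 0.261, the fit left 5 residual degrees of freedom, and the prior added 2.76. This correlation was not estimated precisely: it was 0.078 without replicate 1 and 0.517 without replicate 4 at 40 weeks, and 0.53 without the shift. P-values were adjusted by Benjamini and Hochberg over all 44397 features, with 0.05 as the threshold. Ages share one estimate of the spread, because 2 samples at 3 weeks and 2 at 12 weeks are too few on their own. The number of arrays limits the precision: the median standard error was 0.466 log2 units for 12 against 3 weeks and 0.375 for either comparison with 40 weeks.

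The fit was tested on simulated values for all 44397 features with the estimated spread and array correlation, in which 200 features were changed. For 12 against 3 weeks it recovered 0% of changes of 1 and of 2 log2 units and 75.5% of changes of 3 log2 units. For 40 against 12 weeks it recovered 0%, 32.5% and 90.5%, and for 40 against 3 weeks 0%, 41.5% and 87.5%.

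A feature was taken to lie at the floor of a sample when its intensity was at most 1.5 times the 10th percentile of 51 neighbouring features. Groups of features with near-identical profiles were searched for without use of the ages. Features above the dimmest 40% with at least 5 neighbours within 0.25 log2 units (root mean square over the 8 samples), making up at least a share of 0.3 of those within 0.75, were joined, and groups and further features within 0.5 of a group's median profile were added. In shuffled values this search found 0 groups. With 5 groups of 32 features planted at an SD of 0.15 log2 units it found 5, with 96.9% of their features and 0 others. Both trials ran only the joining of neighbours. The addition of features within 0.5 of a median profile was not tried, so the trials do not cover the features it added. Shuffling also removed all likeness between features other than in brightness. These groups were looked for after the data had been examined.

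The planned rule named the largest rises and falls among genes past the threshold whose samples did not overlap and whose mean lay above the median of all features, or, where too few passed, those with the smallest p. Here at most 2 features per direction and comparison were named by that order. The condition that they lie outside the groups of near-identical features was added after those groups had been seen. Places on the array were taken from feature numbers in rows of 85 columns, the period at which dim values recurred, which gives 532 rows up to feature number 45220. Likeness of samples was measured over 21877 features, those above the median level and outside these groups, as the SD of the log2 difference of a pair. The share of variation that followed age, title code, slide or dye was tested with an exact permutation test over all partitions of the samples into groups of the same sizes. This test was not among those planned. Partitions that exchange only whole arrays or the dyes within arrays were also added after seeing the data. The choices varied, as fixed before the data were examined, were no array block, the array or the replicate number as a fixed block, the slide as a block, fits within a slide or dye, 40-week samples averaged by code, quantile normalization, 2 filters on dim features, another variance model, and leaving out each sample. A further alternative, the shift by the 75th percentile, was already the setting used. The title code as a block, other scalings, and leaving out the groups of near-identical features were added after seeing the data. Structure was computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.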

Results

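Gene expression in the brain of female mice was profiled at 3 ages, in 2 samples at 3 weeks, 2 at 12 weeks and 4 at 40 weeks, to compare stages of reproductive life. The 40-week samples were labelled with Cy5 and the younger samples with Cy3, so age and dye cannot be told apart in the comparisons with 40 weeks. The 12-week and 3-week samples shared a dye and lay on different slides, each beside 40-week samples. Median intensity ranged from 93.4 in replicate 2 at 3 weeks to 158.9 in replicate 1 at 40 weeks. Between 17.5% and 27.5% of features lay at the floor of a sample, 8.5% lay there in all 8 samples, and 28789 features (64.8%) lay above it in all 8. The highest intensity of a sample was 185354 to 304384 in Cy3 and 47740 to 111636 in Cy5. Because the files do not pair features with genes, results are given for array features by number.

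The comparison of 12 with 3 weeks asks what differs between young adult and prepubertal brain. Among non-overlapping features above the median level and outside the near-identical groups, feature 44357 had the lowest p of those higher at 12 weeks. It stood at 1.98 ± 0.05 log2 units at 12 weeks (SD, n = 2), relative to the upper quartile of its sample. At 3 weeks it stood at -3.21 ± 1.64 (SD, n = 2). Its difference was 5.24 log2 units (SE 0.65, limma adjusted p = 0.292), which did not pass the threshold. Without replicate 1 at 3 weeks the difference was 6.33 (limma adjusted p = 0.0322), and without replicate 2 at 3 weeks it was 4.21 (limma adjusted p = 0.0454), with adjusted p up to 1.0 over all alternatives. Feature 18132 stood 2.89 log2 units above its 3-week level (SE 0.45, limma adjusted p = 0.374). In the other direction, feature 32982 differed by -2.05 (SE 0.33) and feature 5883 by -3.08 (SE 0.55), both with a limma adjusted p of 0.393; for feature 32982 it was 0.0484 without replicate 1 at 3 weeks and up to 1.0 over all alternatives. All 4 features were chosen from those in which the samples of the 2 ages did not overlap, so that lack of overlap is not a finding.

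With limma, 0 of the 44397 features passed at 12 against 3 weeks, and the smallest adjusted p was 0.149. An unadjusted limma p under 0.05 was reached by 5135 features, 1833 higher and 3302 lower at 12 weeks. Chance gives 2220 only if all ages vary alike. The SD of the log2 difference between replicates averaged 0.683 at 40 weeks, against 0.958 at 12 and 1.149 at 3 weeks. The shared spread may therefore be too small here. The median change of all features was -0.15 log2 units, against 0.01 with quantile normalization, so the tilt to lower may follow from scaling. Among the 21877 brighter features, the 12-week and 3-week samples, which also differ in slide, did not overlap in 32.6%. Splits of these samples by title code separated 46.1% and by neither 21.3%. Every feature separates in exactly 1 of these splits, so the shares depend on one another. Chance gives 33.3% to each only where no split is favoured, so 32.6% does not exclude an effect of age or slide. When each 12-week sample was set against the 3-week sample of the same title code, 332 features were more than 2-fold higher at 12 weeks in both pairs, 159 were more than 2-fold lower in both, and 357 moved beyond 2-fold in opposite directions. The correlation of these paired differences across features, which are not independent replicates, was 0.07. The count of 0 rose to 1148 without replicate 1 at 3 weeks, 177 higher and 971 lower at 12 weeks, and to 16 without replicate 2 at 3 weeks, 14 higher and 2 lower. In these fits the remaining 3-week sample is assumed to vary like the other ages. Without replicate 1 it is replicate 2, which was over 4-fold above every other sample in at least 576 features.

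The comparison of 40 with 12 weeks asks what differs between later reproductive life and young adulthood. Feature 25889 was 22.6-fold higher at 40 weeks, a difference of 4.50 log2 units (SE 0.33, limma adjusted p = 0.00236), with levels of -1.46 ± 0.51 at 40 weeks (SD, n = 4) and -5.88 ± 0.30 at 12 weeks (SD, n = 2). Feature 25030 was 21.0-fold higher, by 4.39 log2 units (SE 0.28, limma adjusted p = 0.00236). Feature 4169 fell by 3.43 log2 units (SE 0.47, limma adjusted p = 0.0247), from 0.83 ± 0.75 at 12 weeks to -2.65 ± 0.24 at 40 weeks (SD, n = 2 and n = 4). Feature 18132, one of those with a higher value at 12 than at 3 weeks, was lower at 40 than at 12 weeks by 5.68-fold (log2 difference -2.51, SE 0.36, limma adjusted p = 0.0314). Over 23 alternatives the call of feature 4169 passed in 12, that of feature 18132 in 11, and those of features 25889 and 25030 in 17 each. With the groups of near-identical features left out, the limma adjusted p was 0.096 for feature 4169 and 0.12 for feature 18132. For features 25889 and 25030 it was 0.00985. Every difference named here is of Cy5 against Cy3 as well as of age.

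In all, limma called 225 features between 40 and 12 weeks, 212 higher and 13 lower at 40 weeks. Of these, 161 belonged to groups of features with near-identical profiles, and all 161 were higher. Outside the groups 51 features were higher and 13 lower. These 64 became 35, 32, 66 and 115 without replicates 1, 2, 3 and 4 at 40 weeks and 438 when either of the 3-week samples was left out, and the calls lower at 40 weeks, over all features, became 2, 2, 4, 44 and 207. In 22 of the called features all samples of 1 age lay at the floor. The smallest called change was 1.48 log2 units. Of the 51 higher features, 42 had 3-week levels nearer the 12-week than the 40-week mean. Whether any feature passed depended on both 12-week samples and on the block: 0 passed without replicate 1 or without replicate 2 at 12 weeks, 0 with the array or the replicate number as a fixed block, and 0 within slide 1 alone, while 728 passed when either of the 3-week samples was left out. These 5 fits with 0 calls hold 1 sample at 12 weeks or fewer degrees of freedom. In them the difference of feature 25889 was 4.25 to 4.72 (limma adjusted p = 0.0612 to 0.165), against 4.50, and that of feature 4169 -3.99 to -2.94 (limma adjusted p = 0.117 to 0.296), against -3.43. A further fit with 0 calls averaged the 40-week samples by code. There the difference was 4.42 for feature 25889 (limma adjusted p = 0.137) and -3.48 for feature 4169 (limma adjusted p = 0.439). Of the 225 calls, 94.2% were higher, against 78.9% with quantile normalization, 74.9% without a shift and 55.6% with cyclic loess.

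The comparison of 40 with 3 weeks spans the whole age range of the series. Feature 17714 was 18.3-fold higher at 40 weeks, by 4.2 log2 units (SE 0.34, limma adjusted p = 0.00302), with levels of -1.54 ± 0.39 at 40 weeks (SD, n = 4) and -5.81 ± 0.51 at 3 weeks (SD, n = 2). Feature 25030, also higher against 12 weeks, was higher by 4.13 log2 units (SE 0.28, limma adjusted p = 0.00302). Features 17714 and 25030 each passed in 19 of 23 alternatives; in the other 4 the limma adjusted p of both was 0.142 with the array and 0.19 with the replicate number as a fixed block, 0.386 within slide 2 and 0.186 with 40-week samples averaged by code, with differences of 3.96 to 4.55. Feature 4169 fell by 3.33 log2 units (SE 0.47, limma adjusted p = 0.0294), as it did against 12 weeks. The difference was -2.51 without replicate 1 and -4.22 without replicate 2 at 3 weeks, and it passed the threshold in 10 of 23 alternatives. Feature 43937, a bright feature, was lower at 40 than at 3 weeks by 1.64 log2 units (SE 0.24, limma adjusted p = 0.0319). Its levels were 6.79 ± 0.16 at 3 weeks (SD, n = 2), 6.57 ± 0.30 at 12 weeks (SD, n = 2) and 5.14 ± 0.11 at 40 weeks (SD, n = 4). The highest intensities were also lower in Cy5 than in Cy3, so this difference cannot be told apart from one of dye. Feature 43937 passed the threshold in 6 of 23 alternatives. With quantile normalization its difference was -0.70 (limma adjusted p = 0.155). With the title code as a block its adjusted p was 0.0598, and over all alternatives it ranged from 0.00343 to 0.963.

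**Figure D1:**
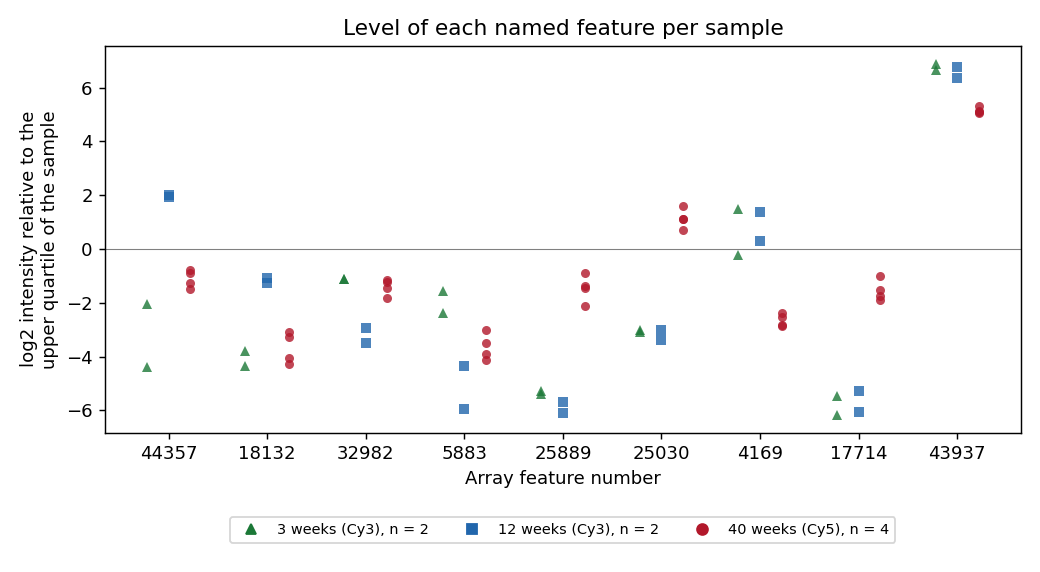
Level of each of the 9 features named for the 3 comparisons, in log2 units relative to the upper quartile of the sample, with 1 point per sample. Triangles are 3-week samples (n = 2), squares 12-week samples (n = 2) and circles 40-week samples (n = 4). Features 25889, 25030 and 17714 are higher in the 4 samples at 40 weeks than in the 4 younger samples, and feature 4169 is lower.

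In all, limma called 277 features between 40 and 3 weeks, 200 higher and 77 lower at 40 weeks. The groups of near-identical features held 125, all higher, and outside them 75 features were higher and 77 lower. Without replicates 1, 2, 3 and 4 at 40 weeks, the higher calls over all features became 44, 53, 58 and 138. The lower calls became 2, 2, 4 and 44. In 67 of the 277 called features all samples of 1 age lay at the floor. The 12-week levels were nearer the 40-week than the 3-week mean for 42 of the 75 higher and 35 of the 77 lower features. The number of calls varied with single samples: it was 46, 55, 62 and 182 without replicates 1, 2, 3 and 4 at 40 weeks, 60 when either of the 12-week samples was left out, 4832 without replicate 1 at 3 weeks and 551 without replicate 2 at 3 weeks. Without replicate 1 at 3 weeks most calls were lower, and without replicate 2 most were higher. Each of these fits holds 1 sample at 3 weeks and takes its spread from the other ages. Without replicate 1 that sample is replicate 2, which was over 4-fold above every other sample in at least 576 features. The turn in direction is therefore not a result about age. Outside the near-identical groups the count of 152 fell to 10, 18, 26 and 75 without replicates 1, 2, 3 and 4 at 40 weeks and to 22 when either of the 12-week samples was left out, and rose to 4666 and 280 without replicates 1 and 2 at 3 weeks. It was 0 with the array or the replicate number as a fixed block and 0 within slide 2 alone. Of the calls, 72.2% were higher, against 61.0% of the 667 calls with quantile normalization, 61.1% without a shift and 56.8% with cyclic loess.

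Both comparisons used the same 40-week samples. Of the features higher at 40 weeks, 149 were called against both younger ages, and 125 of these were near-identical features. Independent lists of these sizes would share 0.96, and 20 simulations of unchanged ages with the same 40-week samples shared 16.1 on average and 23 at most among the same numbers of top features. Outside the groups 24 were shared, with 0.09 for independent lists and 4.3 on average and 12 at most in the simulations. Of those lower at 40 weeks, 4 were shared, with 0.02 for independent lists and up to 4 in the simulations. The simulations treat features as independent and hold no copies, dye or title code effects. Over 21877 features the log2 changes of both comparisons correlated with r = 0.38 across features, and simulated unchanged ages against the same 40-week samples gave 0.23. The covariance was 0.107, against 0.0417 in the simulation, a difference of 0.065. With the 40-week samples split by slide, so that none was used in both, r was 0.54 and the covariance 0.135. Dye is shared by both comparisons in every version of this measure, and each comparison holds 1 array of each title code. The simulation contains neither, so the excess over it is not that of age alone.

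The groups of near-identical features numbered 12 and held 321 features. In 9 groups of 30 to 36 features, 290 in all, the mean over the 40-week Cy5 samples exceeded that over the Cy3 samples by 1.75 to 3.85 log2 units, while features of a group differed by an SD of only 0.11 to 0.22 within a sample. Replicate 2 at 3 weeks was above the other 3 Cy3 samples in all 9 groups, by 0.49 to 2.83 log2 units over their mean. Its upper quartile was 1130.5, against 1917.3 to 2061.2 in the other Cy3 samples. The shift raises all its levels by that gap, so the smaller of these excesses can come from the shift alone. Group 10, with 10 features, had lower levels in Cy5 on all 4 arrays, with a mean log2 difference of -2.29. Without the groups, limma called 26 features at 40 against 12 weeks, 25 higher and 1 lower, 28 at 40 against 3 weeks, 23 higher and 5 lower, and 0 at 12 against 3 weeks.

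**Figure D2:**
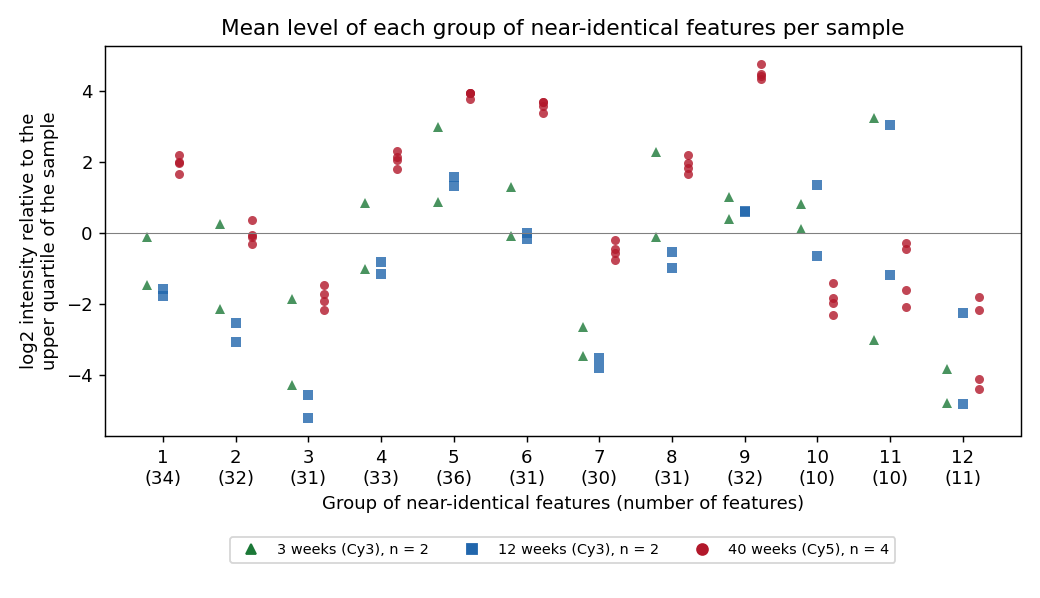
Mean level per sample of the 12 groups of near-identical features, in log2 units relative to the upper quartile of the sample, with the number of features under each group number. Triangles are 3-week (n = 2), squares 12-week (n = 2) and circles 40-week samples (n = 4). In groups 1 to 9 the mean of the 40-week samples lies above that of the younger samples, by 1.75 to 3.85 log2 units, and in groups 10 and 11 below it.

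The 3-week and 12-week samples lay as far from their own replicate as from the samples of the other younger age. The SD of the log2 difference was 1.149 between both 3-week samples and 0.958 between both 12-week samples, and it ranged from 0.896 to 1.153 between a 12-week and a 3-week sample. Among the 40-week samples it ranged from 0.481 to 0.795, with the lowest value between replicates 1 and 3, which share title code A1B. Replicates 2 and 4, which share A2B, lay at 0.697, and replicates 3 and 4, which share a slide and not a code, at 0.609. Age divides the samples into 3 groups and title code, slide and dye into 2. More groups take a larger share by chance, so the shares of variation are not on one scale. Age accounted for 31.1% of the variation, and 59 of 210 partitions of the samples, the real one included, gave as much (exact permutation p = 0.281, adjusted over 4 factors p = 0.375). Title code accounted for 26.9%, the highest of 35 partitions into 4 and 4 (exact permutation p = 0.0286, adjusted p = 0.114), the smallest p these partitions can give. Slide accounted for 20.3% (exact permutation p = 0.0857, adjusted p = 0.171) and dye for 14.5% (exact permutation p = 0.514, adjusted p = 0.514). This test was not planned, and its partitions exchange samples freely, although samples lie in pairs on arrays. With whole arrays exchanged only 3 partitions remain, so no p can fall below 0.333: the exact permutation p was 0.333 for title code, 0.667 for slide and 0.667 for age with the dye held. With dyes exchanged within arrays (8 partitions) it was 0.25 for dye. With the title code as a block, limma called 217 features at 40 against 12 weeks, 221 at 40 against 3 weeks, and 0 at 12 against 3 weeks, where 6848 had an unadjusted p under 0.05. Within 1 code, 12 and 3 weeks have 1 sample each, so no test was made there.

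**Figure D3:**
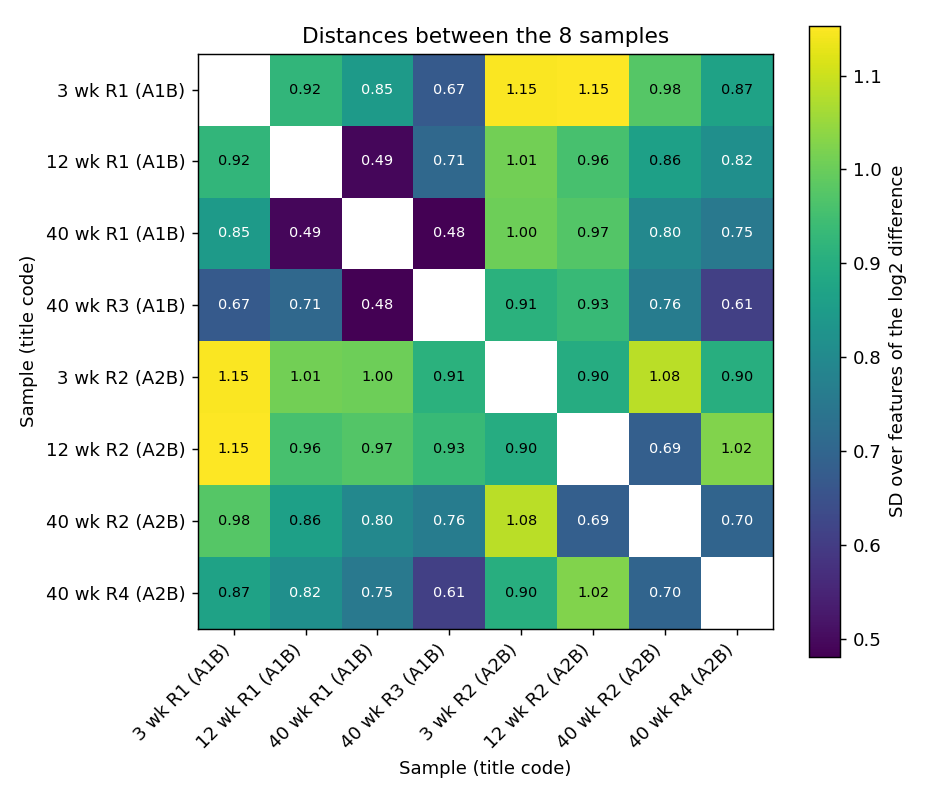
SD over 21877 features of the log2 difference for each pair of the 8 samples, which are ordered by title code and then by age. Darker cells are closer pairs; replicates 1 and 3 at 40 weeks are closest (0.481), and replicate 1 at 3 weeks and replicate 2 at 12 weeks are farthest apart (1.153).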

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

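The tests of explanations in this part were chosen only after the patterns had been seen. Among the 4 samples at 40 weeks, 1 of 24 measures had a sample far from the others: replicate 1 was lowest for group 5 of the near-identical features, at 3.79 log2 units. The criterion was Dixon's at 95%, which 5.0% of simulated sets of 4 normal values met.

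Some differences between a 40-week sample and the younger sample on its array ran in opposite directions, and these oppositions were not tested. Group 11 of the near-identical features averaged 1.74 log2 units higher at 40 weeks on both arrays of code A1B and -4.98 on both arrays of code A2B. Between arrays with 12-week and with 3-week samples, the mean difference was 1.33 and -1.48 for feature 5883, -2.5 and 0.38 for feature 18132, 1.69 and -0.2 for feature 32982, and -3.16 and 2.2 for feature 44357. These 4 features had been named for their difference between 12 and 3 weeks, so their opposition follows in part from that choice.

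Most features called higher at 40 weeks against both younger ages came from few profiles. Of these 149 features, 83.9% belonged to 4 of the groups of near-identical features, so a candidate explanation for their number is a few probes printed in many copies on the array. Copies do not explain why the level was higher at 40 weeks. The files do not say what these features measure, so whether they are control probes or measure brain RNA could not be checked. The 24 features outside the groups are not covered by copies. Dye bias stays open: the median absolute difference between 12 and 3 weeks, both in Cy3, was 0.59 log2 units in these features, against a median of 3.63 between 40 and 12 weeks, and age and dye cannot be told apart because every 40-week sample carried Cy5. An effect of age remains possible and untested.

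Arrays that share a title code resembled one another: across features, the log ratios of arrays 2 and 4, which compare 40 weeks with different ages, correlated with r = 0.76, while r was 0.21 for the 12-week arrays and -0.09 for the 3-week arrays. For arrays 1 and 3 it was 0.20, so the likeness was mainly that of code A2B. Uneven signal over the array surface is argued against, since means of 323 tiles of 28 rows and 5 columns carried 1.5% of the covariance of both arrays. A dye trend with brightness is argued against because means of brightness bins carried 2.2% of it, and features near the floor by an r of 0.78 in the brightest 25%. What the code stands for, a shared RNA, or the position on the slide, stays open and was not tested.

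Replicate 2 at 3 weeks was over 4-fold above every other sample in 576 features, against 0 to 25 features for any other sample, and over 4-fold below every other in 104, against 79 for replicate 1 at 3 weeks. A feature counted as above only if the sample's own level also exceeded a lower limit. The count below had no such condition, so these counts are not alike. The shift raises all levels of this sample, whose upper quartile was 1130.5, against 1917.3 to 2061.2 in the other Cy3 samples. A damaged area is argued against, since the fullest of 50 tiles of the array held 4.0% of the 576, and the fullest of 17 column strips 8.2%. An effect of the array on both channels stays open, because its test cannot decide it. The 40-week sample there, replicate 4, exceeded the other 40-week samples by a median of 0.83 log2 units in these features. That is 22.3% of the excess of 3.72 in replicate 2 at 3 weeks, and replicate 4 was the second highest sample in 31.6%. However, its upper quartile was 1156.7, against 1997.3 to 2131.5 in the other 40-week samples. The shift raises its levels by that gap, so its excess and rank can come from the shift alone. RNA shared within code A2B stays open too: replicate 2 at 12 weeks was second highest in 56.2%, but replicate 2 at 40 weeks, of the same code, was so in only 1 feature, with a median level of -5.53 as in the samples of the other code. A biological difference of this sample was not tested.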

How the results depend on the processing

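The title code as a block, the other scalings and leaving out the near-identical features were tests chosen after seeing the data. At 12 against 3 weeks, the count stayed at 0 in 20 of 23 alternatives, with 1137 to 8142 features at an unadjusted limma p under 0.05. Quantile normalization gave 2, and leaving out 1 sample 0 to 1148. At 40 against 12 weeks (225) limma gave 355 with a variance trend and robust prior, 550 without a shift, 394 with cyclic loess and 26 without the near-identical features; leaving out 1 sample gave 0 to 728. At 40 against 3 weeks (277) it gave 154 without an array block, 57 with slide as a block, 667 with quantile normalization, 681 without a shift and 28 without the near-identical features; leaving out 1 sample gave 46 to 4832.

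With the array as a fixed replicate block both counts were 0 (2820 and 3636 features at an unadjusted p under 0.05), with the replicate number as a block 0 (2101 and 6661), within 1 slide 0 (3573 and 1623), and with 40-week samples averaged by code 0 (4907 and 2617). These fits leave fewer degrees of freedom. No array correlation could be estimated within a slide, so none was used there. The labels do not say that numbers pair samples; replicate 1 minus replicate 2 correlated across features at 0.31 between 12 and 3 weeks, 0.64 between 40 and 12 weeks and 0.04 between 40 and 3 weeks; replicates 3 and 4 at 40 weeks, on the 3-week arrays, gave 0.23 with 3 weeks, -0.01 with 12 weeks and 0.44 with replicates 1 and 2 at 40 weeks. The cause of the other changes was not tested. The median change of all features at 12 against 3 weeks was -0.15 log2 units, 0.01 with quantile normalization and 0.08 without a shift. None of 184 alternatives for the 8 named 40-week differences changed direction, and 111 stayed past the threshold. All 8 had been chosen as large differences without overlap, so the lack of a reversal was largely set by that choice. Features 25030 and 4169 each count as 2 of the 8. The share that followed title code, 26.9%, was 23.4% to 34.0% in 14 alternatives; in 5 of them, with 23.4% to 28.8%, 2 of 35 partitions gave as much and the exact permutation p moved from 0.0286 to 0.0571. Over all features slide had 0.0286 and code 0.0571. The mean over probes of a gene and gene list tests were not run, and the 75th percentile shift was already in use. Signal over the floor limits 22 and 67 calls.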

Other observations

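The counts in this part come from tests chosen after seeing the data, over the 21877 brighter features outside the near-identical groups. Splits of the 4 samples at 40 weeks into pairs gave 1092 features without overlap and at least 2-fold apart when the pairs followed title code, 507 when they followed slide and 119 when they followed neither. Among the 4 Cy3 samples the numbers were 3126 by title code, 1230 by age and slide together, and 770 by neither. Pairs did not overlap in 55.5% of features by code at 40 weeks and in 46.1% by code in Cy3, where chance gives 33.3%.

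Among the same features, the log ratio of 40 weeks over the younger age was beyond 2-fold in opposite directions on the arrays of both codes in 39 features, against 1 feature for arrays with 12-week and 3-week samples and 2 for the crossed pairing. Of the 21877 features, 25 were beyond 2-fold and positive on all 4 arrays, and 33 were beyond 2-fold and negative on all 4.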
